A study of Mus musculus and Rattus norvegicus with 5 samples.

How the data were processed

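Single cells of 5 newborn forebrains were measured with droplet 3' RNA sequencing: 1 WT mouse, 1 WT rat and 3 chimeras, with 1 library each. The deposited matrices hold UMI counts per barcode and gene, made by the authors with Cell Ranger (written as 3.1 and as 3.1.0) against a combined mouse (GRCm38.p6) and rat (Rnor_6.0) reference, per the submitters' processing notes. Aligner settings are not given in the sources used here. The matrices list 22623 mouse genes, 25399 rat genes and 1 reporter, tdTomato. The chimera labels give the host strain and genotype, while the strain of the rat stem cell line is not given in the sources used here. No rat annotation was at hand, so rat genes carry the names of the deposited files.

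A barcode was called rat when at least 0.9 of its UMIs lay on rat genes, mouse when at most 0.1 did, and mixed otherwise, with tdTomato counted on the rat side. Cells needed at least 500 genes of their own species and under 15% mitochondrial UMIs. Doublets within a species were predicted with the scrublet method in scanpy 1.11.5 (expected rate 0.08, score limit 0.3) and removed: 2.66% of the WT mouse, 2.23% of the WT rat and 1.16%, 2.09% and 1.69% of the chimera barcodes that passed. Mixed barcodes were left out. Median genes per mouse cell were 3027 in the WT mouse and 2834, 2679 and 2872 in the chimeras, and per rat cell 2225 in the WT rat and 1909, 1838 and 2111 in the chimeras. The median share of mitochondrial UMIs was 6.96% in WT mouse cells and 5.52%, 6.14% and 6.23% in mouse cells of chimeras. In rat cells it was 7.84% in the WT rat and 6.60%, 7.24% and 7.41% in the chimeras. Whether this goes with the lower oxidative phosphorylation genes below was not tested. UMIs of the other species made up a median of 1.16% in WT rat cells, of 2.11%, 2.40% and 2.22% in rat cells of chimeras, of 0.0532% in WT mouse cells and of 0.528%, 0.283% and 0.404% in mouse cells of chimeras. In the WT libraries, 466 mouse genes and 62 rat genes had more than 0.1 of their own-species level in the other species.

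Cells of each species were clustered together over libraries (2000 variable genes, 30 principal components, 15 neighbours, leidenalg 0.10.2 at resolution 1, seed 1) into 37 mouse and 31 rat clusters. Clusters were named from marker lists fixed before the data were examined: at least 3 markers detected in 20% of cells, a mean score of at least 0.5 log2, and a check of the 10 leading genes. Naming used a pseudocount of 0.05 and the check of leading genes 0.2 counts per 10000; with 0.05 in the check, cluster M33 would have had a striatal gene and no marker of its own among its leading genes. M12, M24 and R11 stayed unnamed. M12 and R11 had median UMI counts of 0.572 and 0.519 of their library. R13 did not pass the check for endothelial cells.

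Rat shares and class shares carry exact binomial intervals. Classes were compared over animals with exact permutations, whose smallest two-sided p is 0.25. For genes, the deposited counts were summed per library, species and class, for classes with at least 50 cells in each library, and tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM, filterByExpr) with Benjamini-Hochberg adjustment at 0.05. Chimera against WT left 2 residual degrees of freedom, the difference between the rat and mouse comparisons 4 and rat against mouse cells within chimeras 2. The last test used the animal as block, because rat and mouse cells came from the same animal and library by design. With 1 WT animal per species, the lone WT library was assumed to vary like the chimeras. Genes were matched between genomes by symbol (15953 genes). WT rat was compared with WT mouse as folds only.

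Of 23 gene lists fixed before the data were examined, 22 could be tested, with camera in limma 3.58.1 (preset correlation 0.01), and with an estimated correlation and fry as alternatives. The proteasome list was added later. With an estimated correlation, camera rests on the 2 or 4 residual degrees of freedom and could hardly call a list. Even the proteasome list, lower in 34 of 34 genes in mouse excitatory neurons, was not called there beside the other lists (camera, Benjamini-Hochberg adjusted p = 0.116). A list not called with an estimated correlation is therefore no evidence against its change. Named genes followed a rule fixed before the data were examined: the 5 highest and 5 lowest log2 differences among called genes with a mean of at least 20 CPM, all chimeras on the same side and a real gene name, then up to 2 called members per list, and up to 4 of each called list. From these, a shorter set was taken for the text, and some genes that the rule picked are not reported here. Rat symbols that occur more than once were not named.

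The test was tested on simulated data drawn from the means and sizes of the excitatory neuron libraries with 200 changed genes. At 1.5-fold, 2-fold and 4-fold it recovered 8.96%, 53.7% and 93.9% in the rat comparison (12062 genes), 7.46%, 49.3% and 90.9% in the mouse comparison (13613 genes), 0%, 14.9% and 80.3% in the difference (12328 genes) and 73.1%, 97.0% and 100% within chimeras (11354 genes). Unchanged genes were 4.59%, 2.97%, 0% and 4.26% of the calls. In the simulation, 1.5-fold changes were mostly missed except within chimeras. It gave all genes the same spread and changed only 200, so its recovery does not carry over to the data. In rat excitatory neurons 3438 genes were called, 1189 of them at least 2-fold, and in mouse ones 4268 and 1153. Alternatives were species limits of 0.8 and 0.2 and of 0.95 and 0.05, no cell filter or 1000 genes and 10% mitochondrial UMIs, doublets kept, resolutions 0.5 and 2, DESeq2 1.42.0, RLE size factors, other expression filters, thinned counts, a 1.5-fold minimum (glmTreat), removal of cross-mapping genes and leaving out each chimera. Other versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.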

Results

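Forebrain cells of 5 newborn animals (postnatal day 0) were profiled by droplet single-cell RNA sequencing, with 1 library per animal. The animals were 1 WT mouse (B6D2F1/J), 1 WT rat (Sprague-Dawley) and 3 chimeras. A chimera was a B6D2F1/J mouse embryo lacking Hesx1, a homeobox gene needed for forebrain formation, that had received rat embryonic stem cells, so that its forebrain could hold mouse and rat cells side by side. The deposited matrices held 16853 barcodes for the WT mouse, 10962 for the WT rat, and 8702, 12204 and 9967 for chimeras 1, 2 and 3. Their total UMI counts were 110950889, 77940306, 57641164, 81283819 and 76828492 in the same order. After the filters, 10559 WT mouse cells and 9614 WT rat cells remained, with 7937, 10655 and 8885 cells of both species in chimeras 1, 2 and 3. Mouse cells had a median of 7981 UMIs in the WT mouse and of 6648, 6254 and 7190 in the chimeras. Rat cells had a median of 5862.5 UMIs in the WT rat and of 4667.5, 4395 and 5703 in the chimeras, so WT cells were the deeper ones in both species.

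The share of rat cells asks how much of each forebrain came from the injected stem cells. Rat cells made up a large part of all 3 chimeric forebrains, and that part differed between animals by more than counting error. Chimera 1 held 56.2% rat cells (4464 of 7937, exact 95% Clopper-Pearson interval 55.1 to 57.3%), chimera 2 held 29.2% (3115 of 10655, 28.4 to 30.1%) and chimera 3 held 41.9% (3721 of 8885, 40.9 to 42.9%). The mean was 42.5% ± 13.5 (SD, n = 3). Measured the same way, the WT mouse library held 0 rat cells and the WT rat library 0 mouse cells among the cells that passed the filters, which allows wrongly called shares of up to 0.0277% and 0.0305%. Barcodes with UMIs of both species in excess of the limits, which can be droplets with a cell of each species, made up 3.98%, 4.52% and 4.205% of the filtered barcodes of chimeras 1, 2 and 3 and were left out. Hesx1, the gene disrupted in the host, was too low to check the genotype: the mouse gene had 1 UMI in the WT mouse library and 0 in the chimeras, and the rat gene had 0 UMIs in all 5 libraries.

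The red fluorescent reporter tdTomato, counted as a rat feature, marked most rat cells of the chimeras and few mouse cells. At least 1 tdTomato UMI was found in 75.5% of the rat cells of chimera 1 (3369 of 4464, exact 95% interval 74.2 to 76.7%), 64.8% in chimera 2 (2019 of 3115, 63.1 to 66.5%) and 70.7% in chimera 3 (2629 of 3721, 69.2 to 72.1%), with median depths of 4779, 4521 and 5848 UMIs. The background in mouse cells of the same libraries was 1.61%, 0.451% and 0.813%, at median depths of 6696, 6277 and 7233 UMIs. Thinned to 2000 UMIs per cell, the shares were 47.8%, 38.7% and 38.7% in rat cells and 0.323%, 0.147% and 0.195% in mouse cells. No WT cell that passed the filters carried a tdTomato UMI, which allows shares of up to 0.0284% in the WT mouse and 0.0312% in the WT rat. Over all barcodes, the WT mouse library held 13 tdTomato UMIs and the WT rat library 0. Among the 3 rat classes measured, radial glia or astrocytes were the most often marked (86.8%, 83.7% and 79.2%), and excitatory (77.3%, 65.0% and 72.3%) and GABAergic neurons (62.4%, 66.1% and 44.2%) were less often marked. After thinning the order was 63.6%, 61.5% and 42.9% for radial glia or astrocytes, 45.2%, 35.4% and 36.2% for excitatory neurons and 46.5%, 50.9% and 30.9% for GABAergic neurons.

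The rat share within each cell class asks whether rat cells entered some lineages more than others. Rat cells were found among neurons, progenitors, glia and microglia, but not in equal parts. Excitatory neurons held more rat cells and GABAergic neurons fewer than the pooled neurons in each chimera. Excitatory neurons were 59.2%, 31.8% and 41.1% rat in chimeras 1, 2 and 3, and GABAergic neurons, the inhibitory neurons of the forebrain, were 43.3% (521 of 1202), 5.31% (59 of 1111) and 32.7% (215 of 657). Striatal projection neurons, the output cells of the striatum, were 47.8% rat in chimera 1 (479 of 1002), 2.44% in chimera 2 (5 of 205) and 2.50% in chimera 3 (1 of 40). Against the pooled neurons of the same animal, the rat share was 13.5 points ± 7.94 (SD of the difference, n = 3) lower in GABAergic neurons and 3.41 points ± 1.88 higher in excitatory neurons. The 3 animals moved the same way in both, which gave a two-sided exact sign-flip permutation p of 0.25, the smallest that 3 animals allow. The pooled neurons include both classes, so a lower share in one raises the other relative to the pool, and these differences are not independent of each other. At clustering resolutions 0.5 and 2, GABAergic neurons lay 19.5 points ± 8.51 and 20.4 points ± 9.91 below, with the same exact permutation p of 0.25 at n = 3. Striatal neurons lay 23.1 points ± 15.5 and oligodendrocyte-lineage cells 8.94 points ± 7.73 below the pooled neurons, cycling cells 6.73 points ± 6.52 and intermediate progenitors 7.96 points ± 9.89 above them, each with the same exact permutation p of 0.25 at n = 3. The striatal gap held in each chimera only at resolution 1. In chimera 1, striatal neurons were 72.2% rat (565 of 783) at resolution 0.5 and 56.4% (677 of 1200) at resolution 2, which is 17.1 and 0.457 points above its pooled neurons. Over the 3 chimeras the striatal difference was then -4.59 points ± 23.7 and -15.8 points ± 17.6 (exact sign-flip permutation p = 0.75 and 0.5, n = 3). Cycling cells had an exact permutation p of 0.5 at resolution 0.5, and intermediate progenitors lay 2.31 points below the neurons at resolution 2 (exact permutation p = 0.75, n = 3). Radial glia or astrocytes were 68.1%, 27.0% and 53.5% rat, which was on balance 8.90 points ± 8.28 above the neurons (exact permutation p = 0.5, n = 3). Microglia, which reach the brain from the yolk sac, included rat cells in each chimera (9 of 14, 5 of 28 and 18 of 27 cells). Clusters M4 (mouse) and R13 (rat), compared by number because R13 did not pass the marker check for endothelial cells, held 3 rat cells of 47, 0 of 37 and 8 of 53. Mural cells, the contractile cells of vessel walls, were 44.8%, 4% (1 of 25 cells) and 47.7% rat, and Cajal-Retzius cells 29.4%, 27.8% and 14.9% (each exact permutation p = 0.5, n = 3). Cells of unnamed clusters, which had low UMI counts, were 68.4%, 69.6% and 64.5% rat.

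**Figure D1:**
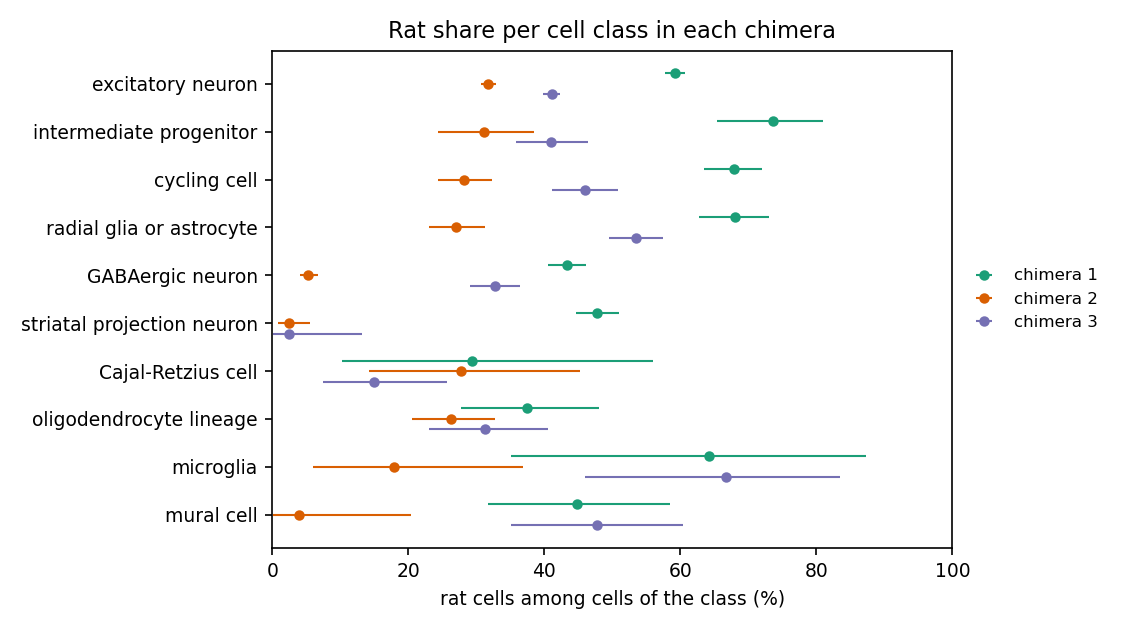
Rat cells as a percent of the cells of each class in the 3 chimeras (1 point per chimera with its exact 95% interval). Excitatory neurons lie at 59.2%, 31.8% and 41.1%, while GABAergic neurons of chimera 2 lie at 5.31%.

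Which subtypes of rat inhibitory neuron were present differed between animals as well. Chimera 2 had almost no rat cells of the clusters that held most GABAergic neurons of the WT rat. Cluster R1, led by Maf, Nxph1 and Sst, held 932 WT rat cells and 67, 0 and 39 cells of chimeras 1, 2 and 3. Cluster R2, led by Lhx8, Zic4 and Nkx2-1, genes of the ventral forebrain, held 1029 WT rat cells and 3, 0 and 0. Cluster R10, led by Crh, Vip, Htr3a, Adarb2 and Prox1, held 452 WT rat cells and 126, 2 and 170. Cluster R18, led by Six3 and Dlx1, held 167 of 9614 WT rat cells and 325 of 4464, 57 of 3115 and 6 of 3721 rat cells of the chimeras, a larger share than in the WT rat in chimera 1, about the same in chimera 2 and a smaller one in chimera 3. Among striatal clusters, R16 (led by Isl1 and Tac1) held 1029 WT rat cells and 13, 0 and 0 chimera cells, R9 (Penk, Adora2a, Drd2) held 447 and 230, 4 and 1, and R25 (Ebf1, Pdyn) held 4 and 236, 1 and 0. These genes define the clusters, so they are no result of their own. R16 and R25 both had Ebf1, Tac1 and Rarb among their leading genes. At the lowest clustering resolution, a cluster led by Isl1, Ebf1 and Tac1 held 1035 WT rat cells and 249, 1 and 0 chimera cells. The split between R16 and R25 therefore does not show that the WT rat and chimera 1 held different striatal subtypes.

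The makeup of the rat cells was compared with that of a rat forebrain. Rat cells of chimeras were richer in excitatory neurons and poorer in GABAergic, striatal and oligodendrocyte-lineage cells than those of the WT rat, and the WT value lay outside the range of the 3 chimeras for each of these classes. Excitatory neurons were 66.0% ± 10.2 (SD, n = 3) of the rat cells of chimeras and 39.4% (exact 95% interval 38.4 to 40.4%) of the WT rat cells. GABAergic neurons were 6.45% ± 4.92 against 26.8%, striatal projection neurons 3.64% ± 6.14 against 15.4%, and oligodendrocyte-lineage cells 1.19% ± 0.53 against 3.05%. For these 4 classes the two-sided exact permutation of the 4 libraries gave p = 0.25, the smallest possible with 1 WT animal. In the WT mouse, striatal neurons were only 3.95% and GABAergic neurons 17.0% of the cells. Among mouse cells of the 3 chimeras, striatal neurons ranged from 0.755% to 15.1%. The extent of the tissue dissected from the 1 WT rat therefore cannot be told apart from these differences and was not tested. The striatal difference did not hold at clustering resolution 2 (5.52% against 9.73%, with 15.2% in chimera 1; exact permutation p = 1.0, n = 3 against 1). The oligodendrocyte-lineage difference did not hold with limits of 1000 genes and 10% mitochondrial UMIs (1.17% against 1.40%, exact permutation p = 0.75, n = 3 against 1). Intermediate progenitors, the short-lived precursors of excitatory neurons, were 2.59% ± 1.08 against 0.603% and cycling cells 5.69% ± 1.30 against 4.26% (exact permutation p = 0.5 each, n = 3 against 1). Radial glia or astrocytes did not differ by more than the spread between chimeras (6.09% ± 2.59 against 5.95%, exact permutation p = 1.0, n = 3 against 1).

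The same comparison in the host asks whether mouse cells beside rat cells kept the makeup of a mouse forebrain. Glia were scarcer and cycling cells more frequent among the mouse cells of chimeras, whereas the WT shares of excitatory, GABAergic and striatal neurons lay within the range of the chimeras. Radial glia or astrocytes were 4.45% ± 1.29 (SD, n = 3) of the mouse cells of chimeras and 9.31% of the WT mouse cells, oligodendrocyte-lineage cells 1.78% ± 0.28 against 3.31%, microglia 0.208% ± 0.086 against 1.03%, Cajal-Retzius cells 0.598% ± 0.438 against 1.16%, and cycling cells 4.57% ± 0.29 against 2.44%. Each of these 5 gave an exact permutation p of 0.25, the smallest possible with 3 chimeras against 1 animal. Excitatory neurons were 61.8% ± 11.3 against 51.8% (exact permutation p = 1.0), GABAergic neurons 14.0% ± 5.53 against 17.0% (p = 0.75, same exact test) and striatal neurons 6.16% ± 7.77 against 3.95% (p = 1.0, same exact test).

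**Figure D2:**
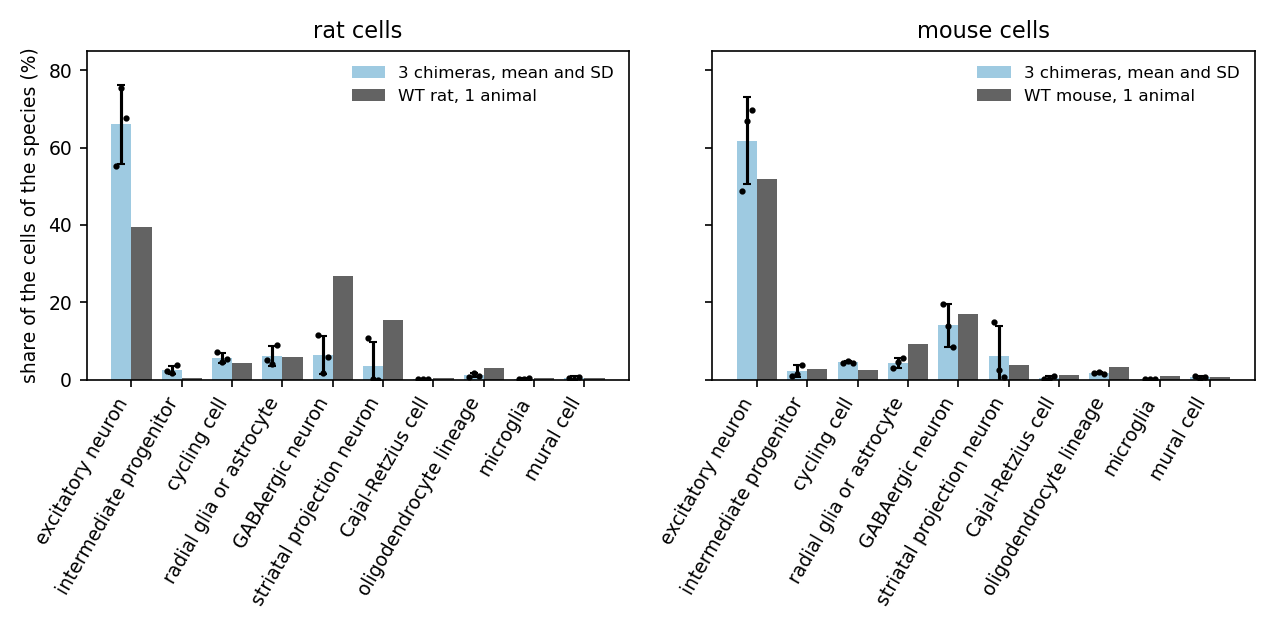
Share of each class among the rat cells and among the mouse cells of each library, in percent; blue bars give the mean of the 3 chimeras with its SD, points the single chimeras and grey bars the WT library. Among rat cells, GABAergic neurons were 6.45% in chimeras and 26.8% in the WT rat.

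Gene expression of rat cells grown in a mouse was compared with that of rat cells grown in a rat, in each class with enough cells. Rat excitatory neurons of chimeras had less RNA for the tubulins Tubb4b and Tubb2a, for the calmodulin-binding synaptic protein Nrgn and for some respiratory-chain subunits, and more for several imprinted genes and for Sox11. Of 12333 genes, 3438 changed (1557 higher, 1881 lower; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1850 did so without chimera 2. The largest rise was in the unnamed locus AABR07039356.2 (ENSRNOG00000051257; log2 difference 11.19 ± 0.33 SE, edgeR Benjamini-Hochberg adjusted p = 4.44e-05), which was chosen after its values were seen and whose identity was not checked, since no rat annotation was at hand. Next came Mrpl43, a mitochondrial ribosome protein (ENSRNOG00000014890; 3.45 ± 0.15, edgeR Benjamini-Hochberg adjusted p = 0.000108), with 79.4, 67.6 and 70.9 CPM in the chimeras and 6.62 CPM in the WT rat, and Jund, an AP-1 transcription factor (3.21 ± 0.23). Whether the strain or line carries a variant at the 3' end of these genes, which would change their counts, was not checked here, nor for Fam111a below. Chd7, a chromatin remodeller, rose by 2.49 ± 0.44, the collagen-crosslinking enzyme Loxl1 by 2.44 ± 0.33 and the small GTPase Gem by 2.26 ± 0.35. Without chimera 1, Chd7 was no longer called (2.43, edgeR Benjamini-Hochberg adjusted p = 0.0727). Nrgn (ENSRNOG00000010688) fell strongly (-4.01 ± 0.19, edgeR Benjamini-Hochberg adjusted p = 0.000381), with 21.8, 14.4 and 14.4 CPM against 271 CPM. The beta-tubulins Tubb4b (-3.01 ± 0.11) and Tubb2a (-2.77 ± 0.12) and the signal peptide peptidase Hm13 (-2.61 ± 0.17) followed. Eif2s3y and Kdm5d, both on the Y chromosome, had 0 UMIs in rat excitatory neurons of the 3 chimeras and 183 and 20.4 CPM in the WT rat, which is at least 2688-fold and at least 299.8-fold lower against a floor of 3 counts over the chimeras. By these Y genes the sex of the rat cells differs between the WT rat and the chimeras.

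Among genes of neuronal maturation, the kinase Camk2a (-2.89 ± 0.40), the surface protein Thy1 (-2.27 ± 0.33) and the cytoskeletal regulator Dpysl3 (-1.29 ± 0.16) fell in rat excitatory neurons, while the microtubule protein Map2 (0.91 ± 0.15) and Sox11, a factor of newborn neurons (1.40 ± 0.18), rose. Of the 22 synapse genes, 2 were higher and 6 lower, the same numbers when adjusted over the list alone (camera with preset correlation, Benjamini-Hochberg adjusted p = 0.00465, and adjusted p = 0.877 with an estimated correlation). The imprinted genes Peg3 (1.5002 ± 0.13), Usp29 (1.46 ± 0.13), Zdbf2 (1.92 ± 0.20) and Sgce (1.30 ± 0.16), which are expressed from 1 parental copy, rose. In that list 8 of 16 were higher and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.542 with an estimated correlation). Oxidative phosphorylation genes were lower in 7 of 15 and higher in 0 (8 lower adjusted over the list alone; camera adjusted p = 0.00465, and adjusted p = 0.797 with an estimated correlation), among them Cox5b (-0.69 ± 0.11) and Sdhb (-0.61 ± 0.11). The AP-1 gene Junb fell (-2.44 ± 0.18) although Jund rose, and the stress factors Ddit3 (1.63 ± 0.17) and Sdf2l1 (1.75 ± 0.20) rose. The glycolytic enzymes Pgk1 (-1.25 ± 0.12) and Gapdh (-1.16 ± 0.15) fell. In cholesterol synthesis Lss rose (1.39 ± 0.13) and Fdps fell (-1.21 ± 0.14). The guidance ligand Efnb2 (1.07 ± 0.18) and the helicase gene Ddx3x (0.63 ± 0.12) were higher. Haemoglobin RNA, which is made by red blood cells, was lower in the neuron profiles: Hbb had 0.686, 1.08 and 0.545 CPM against 43.3 CPM, and all 3 genes of the list fell (camera adjusted p = 8.98e-19, and adjusted p = 0.25 with an estimated correlation; at clustering resolution 2, camera adjusted p = 0.496 and Hbb not called, -3.498). The sex-linked list, which holds Eif2s3y and Kdm5d, had 1 gene higher and 2 lower of 5 (3 and 2 adjusted over the list alone; camera adjusted p = 5.03e-07, and adjusted p = 0.337 with an estimated correlation), with a median above 0 and a mean below it. Different clusters held most excitatory neurons in the WT rat (R3, R5, R6, R7 and R15) and in the chimeras (R23, R24 and R26 to R30), so these values compare mixtures of subtypes.

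Cycling rat cells, the dividing progenitors, had 6 of 13 astrocyte and 6 of 19 cell-cycle genes lower in chimeras than in the WT rat, with neither list called with an estimated correlation, and more RNA for Jund, Klf4 and Vegfa. Their clusters R8 and R19 held cells of the WT rat and of each chimera, but not in equal parts: R19 held 43 of 410 cycling cells in the WT rat and 52 of 319, 24 of 145 and 100 of 196 in chimeras 1, 2 and 3. At clustering resolution 2 a further cycling cluster, R35, held 16 WT rat cells and 57, 35 and 123 chimera cells, and a cluster led by Olig1 and Olig2 held 186 and 80, 91 and 82. Of 9805 genes, 1227 changed (361 higher, 866 lower; edgeR, as above), and 645 without chimera 2. Mrpl43 (4.29 ± 0.32, edgeR Benjamini-Hochberg adjusted p = 2.89e-05), Jund (3.04 ± 0.34), the membrane protein gene Myadm (2.58 ± 0.36), the pluripotency-related factor Klf4 (2.46 ± 0.24) and Fam111a, a protease of replication forks (2.26 ± 0.19), led the rises. The Y genes Eif2s3y and Kdm5d had 0 UMIs in cycling rat cells of the chimeras and 180 and 21.6 CPM in the WT rat, at least 324.6-fold and 39.0-fold lower. Among the other genes named here, the lipid carrier Apoe (-4.76 ± 0.34, edgeR Benjamini-Hochberg adjusted p = 0.00122) fell most, with 41.5, 18.6 and 24.9 CPM against 803 CPM. The calcium-binding S100b (-2.78 ± 0.26), the secreted protein Olfm2 (-2.62 ± 0.28) and Tubb4b (-2.54 ± 0.39) fell too. Of 13 astrocyte genes 6 were lower and 0 higher (10 lower adjusted over the list alone; camera adjusted p = 3.72e-13, and adjusted p = 0.325 with an estimated correlation), including the water channel Aqp4 (-3.15 ± 0.41) and Aldoc (-1.51 ± 0.20). Of 19 cell-cycle genes 6 were lower and 0 higher (10 and 2 adjusted over the list alone; camera adjusted p = 0.00731, and adjusted p = 0.59 with an estimated correlation), including Pcna (-0.96 ± 0.19), Mcm6 (-0.81 ± 0.17) and Rrm2 (-1.46 ± 0.32). Rrm2 was no longer called without chimera 2 (-1.39, edgeR Benjamini-Hochberg adjusted p = 0.0969). Neither Rrm2 (-1.60) nor Aldoc (-0.30) was called at clustering resolution 2 (edgeR Benjamini-Hochberg adjusted p = 0.0624 and 0.746). Oxidative phosphorylation genes were lower in 5 of 15 (11 adjusted over the list alone; camera adjusted p = 0.00504, and adjusted p = 0.59 with an estimated correlation), Ndufa4 among them (-0.85 ± 0.17). Haemoglobin and sex-linked genes were called as lists too (camera adjusted p = 0.00815 and 0.00504, and adjusted p = 0.59 with an estimated correlation for both). The growth factor Vegfa (1.98 ± 0.24) and the sterol sensor Insig1 (1.10 ± 0.21) rose, while Fdps (-1.34 ± 0.19) and the chaperone Hspa8 (-0.87 ± 0.18) fell.

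In rat radial glia or astrocytes of chimeras, 15 of 19 cell-cycle genes were higher and 8 of 13 astrocyte, 7 of 11 immediate early and 4 of 5 antigen-presentation genes lower than in those of the WT rat, and no list was called with an estimated correlation. The class held dividing cells mostly from chimeras: at clustering resolution 2 a cycling cluster, R35, appeared with 16 WT rat cells and 57, 35 and 123 chimera cells, and the class went from 6.09% to 4.19% of the rat cells of chimeras, while cycling cells went from 5.69% to 7.59%. Different clusters held the class: R4 (545 of its 592 cells from the WT rat), led by S100b, Apoe and Aqp4, and R21 (207, 110 and 329 chimera cells, 27 WT cells), led by Hopx and Megf10. The astrocyte differences are therefore in part those that define the clusters. Of 9995 genes, 2477 changed (1087 higher, 1390 lower; edgeR, as above), and 1644 without chimera 2. At clustering resolution 2, 1633 genes were called and 16 of the 2477 had the opposite direction. There 5 of 15 cell-cycle genes were higher (camera adjusted p = 0.00982), a test chosen after seeing the data, with Mki67 at 1.88 (edgeR Benjamini-Hochberg adjusted p = 0.00256), and Cenpf (1.31) and Nusap1 (1.33) were no longer called (0.0949 and 0.25, same adjustment). The interferon list was not called there (camera adjusted p = 0.0763). Fam111a rose by 5.03 ± 0.30 (edgeR Benjamini-Hochberg adjusted p = 5.43e-11), followed by the histone gene Hist1h2ai (3.94 ± 0.45), the cohesin acetyltransferase Esco2 (3.92 ± 0.37), Mrpl43 (3.84 ± 0.32) and the centromere guardian Sgo1 (3.81 ± 0.38). The Y genes Eif2s3y and Kdm5d had 0 UMIs in the chimeras and 178 and 22.1 CPM in the WT rat, at least 249.2-fold and 31.0-fold lower. Among the other genes named here, the cilium-related Fam183a (-5.01 ± 0.50) and Ccdc153 (-4.996 ± 0.38), the endothelial and glial membrane protein Tmem100 (-4.52 ± 0.32) and the neuroendocrine Resp18 (-4.10 ± 0.46) fell most. Ccdc153 is on the marker list of ependymal or choroid plexus cells, so its fall can reflect which cells the class held. Of 19 cell-cycle genes 15 were higher and 0 lower, the same when adjusted over the list alone (median log2 difference 1.85; camera adjusted p = 3.6e-17, and adjusted p = 0.531 with an estimated correlation). Mki67, the usual mark of dividing cells, had 399, 488 and 549 CPM against 42.3 CPM (3.42 ± 0.26), and Cenpf (3.16 ± 0.24), Nusap1 (2.93 ± 0.23) and Ccna2 (3.02 ± 0.28) rose with it. Of 13 astrocyte genes 8 were lower and 0 higher (camera adjusted p = 4.57e-17, and adjusted p = 0.531 with an estimated correlation): the chaperone Clu (-3.66 ± 0.19), S100b (-3.03 ± 0.20) and Apoe (-4.08 ± 0.24) were among them. Of 11 immediate early genes 7 were lower and 1, Jund (2.80 ± 0.25), higher (camera adjusted p = 0.00161, and adjusted p = 0.611 with an estimated correlation), with Junb (-3.24 ± 0.22) and Fos (-1.45 ± 0.18) falling. Antigen-presentation genes were lower in 4 of 5 (camera adjusted p = 0.00169, and adjusted p = 0.531 with an estimated correlation), such as B2m (-2.19 ± 0.19), and interferon genes in 3 of 8 (camera adjusted p = 0.0274, and adjusted p = 0.69 with an estimated correlation), such as Ifitm3 (-3.79 ± 0.32). The lists for oxidative phosphorylation, with Ndufb4 (-1.01 ± 0.19), haemoglobin and sex-linked genes were called with camera adjusted p = 0.0444, 0.0145 and 0.0167, and with an estimated correlation had adjusted p = 0.611, 0.611 and 0.559. Lss (2.00 ± 0.23), Insig1 (1.54 ± 0.21), Vegfa (1.58 ± 0.23) and Peg3 (1.34 ± 0.21) rose, and the SHH receptor Ptch1 (-1.52 ± 0.22) fell.

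In the other rat classes with at least 50 cells per library, 821 of 8977 genes changed in GABAergic neurons (284 higher, 537 lower) and 1004 of 6124 in intermediate progenitors (397 higher, 607 lower; edgeR, as above). The GABAergic values compare different subtypes, since the WT rat cells lay mostly in R1 and R2 and those of the chimeras mostly in R18 and R10.

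Mouse cells of chimeras, which share their animal with rat cells and lack Hesx1, were compared with those of the WT mouse. Mouse excitatory neurons had less RNA for Tubb4b and Tubb3 and for 5 of 9 heat-shock and 14 of 20 oxidative phosphorylation genes, and more for several genes of cortical layers and Sox11. Of 13831 genes, 4268 changed (1899 higher, 2369 lower; edgeR, as above), and 2056 without chimera 2. Among the falls were Asns, the asparagine synthetase (ENSMUSG00000029752, chromosome 6, 7675169 to 7693254 in GRCm38; -2.78 ± 0.11, edgeR Benjamini-Hochberg adjusted p = 0.00106), with 13.6, 14.6 and 15.3 CPM against 92.0 CPM, and Tubb4b (-2.86 ± 0.17). Nr2f2, a factor of caudal and ventral forebrain, fell by 5.53 ± 0.77 and Snhg11 by 3.54 ± 0.45. Nr2f2 also leads cluster M0, which held 603 WT cells among its 610. Without chimera 1, Nr2f2 had an edgeR Benjamini-Hochberg adjusted p of 0.0903 (log2 -5.39), and without chimera 3, Snhg11 had 0.178 (-3.52). Rises were led by the CREB-family factor Creb5 (2.48 ± 0.48), Vegfa (2.37 ± 0.48), the progenitor factor Eomes (2.28 ± 0.31), the actin-binding Rai14 (1.96 ± 0.17) and the scaffold Mpp7 (1.88 ± 0.25). Without chimera 1, Creb5 (2.60) and Vegfa (2.21) had edgeR Benjamini-Hochberg adjusted p of 0.0552 and 0.0633, and without chimera 3 Vegfa (2.26) had 0.179. Eomes (0.99) had an edgeR Benjamini-Hochberg adjusted p of 0.062 at clustering resolution 2. Sox11 rose (1.21 ± 0.16), and Tubb3 (-1.57 ± 0.20), Nrgn (-2.37 ± 0.17) and the neurofilament Nefl (-1.72 ± 0.17) fell. Map2 rose (0.62 ± 0.11), but without chimera 2 it was no longer called (0.61, edgeR Benjamini-Hochberg adjusted p = 0.0625). Of 22 synapse genes 3 were higher and 7 lower (3 and 8 adjusted over the list alone; camera adjusted p = 0.0394, and adjusted p = 0.585 with an estimated correlation; at clustering resolution 2, camera adjusted p = 0.0558).

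**Figure D3:**
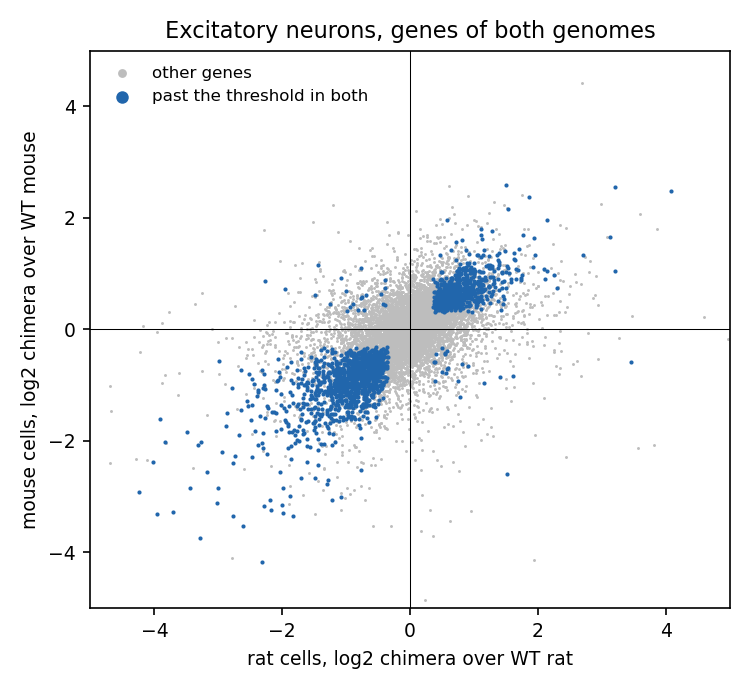
Log2 difference between chimera and WT of each shared gene in rat excitatory neurons (horizontal) and in mouse excitatory neurons (vertical), over 10628 genes, with axes ending at 5. Genes called in the same direction in both species lie along the diagonal, 710 higher and 1123 lower.

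In mouse excitatory neurons, heat-shock genes were lower in 5 of 9 and higher in 0 (8 lower adjusted over the list alone; camera adjusted p = 0.000274, and adjusted p = 0.585 with an estimated correlation). The chaperones Hsp90aa1 (-1.69 ± 0.10) and Hspd1 (-0.94 ± 0.13) were among them. Oxidative phosphorylation genes were lower in 14 of 20 and higher in 0 (15 lower adjusted over the list alone; camera adjusted p = 9.07e-05, and adjusted p = 0.585 with an estimated correlation). Ndufb4 (-1.10 ± 0.09) and Cox5a (-1.02 ± 0.10) were 2 of these. Astrocyte genes, read in neurons at low levels, were lower in 4 of 14 (camera adjusted p = 0.00254, and adjusted p = 0.585 with an estimated correlation). Sparcl1 (-1.27 ± 0.10), Clu (-2.13 ± 0.23) and Apoe (-1.46 ± 0.18) were among these. Genes of deep and upper cortical layers were higher in 6 of 18 and lower in 0 (7 higher adjusted over the list alone; camera adjusted p = 0.000362, and adjusted p = 0.585 with an estimated correlation). Pou3f3 (1.35 ± 0.13), the netrin receptor Unc5d (1.03 ± 0.13) and the corticothalamic factor Tle4 (0.80 ± 0.10) were in the last list. Clusters of different layers held the class, M0, M1, M3, M7, M11, M14, M15 and M19 mostly in the WT mouse and M21, M22, M25, M29, M30 and M32 to M36 mostly in the chimeras, and M29 is led by Unc5d and M33 by Tle4. In the deep-layer clusters M1 and M33 alone, Unc5d had a log2 difference of -0.07, and without M33 Tle4 had -0.23. Fdps (-1.63 ± 0.10) and the imprinted Ndn (-1.95 ± 0.08) fell, while Insig1 (1.34 ± 0.13), the p53 target Trp53inp1 (1.41 ± 0.13), the imprinted Zdbf2 (1.12 ± 0.10) and Fosb (1.70 ± 0.18) rose. Junb fell (-0.98 ± 0.10), as it did in rat cells.

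In mouse GABAergic neurons, as in mouse excitatory neurons, Tubb4b, Tubb3, 5 of 8 heat-shock genes and 16 of 20 oxidative phosphorylation genes were lower in chimeras. The clusters M6, M16, M17 and M18 held the class in the WT mouse and in the chimeras. At clustering resolution 2 its Sst and Lhx6 cells separated by group: M24, led by Sst and Calb1, held 561 WT mouse cells and 36, 27 and 25 chimera cells and M34 held 494 and 26, 11 and 9, against 9 and 97, 132 and 61 in M42 and 41 and 255, 377 and 185 in M43. Calb1 below is therefore in part a gene that separates these clusters. Of 11547 genes, 3888 changed (1687 higher, 2201 lower; edgeR, as above). The calcium buffer Calb1 (-2.99 ± 0.13, edgeR Benjamini-Hochberg adjusted p = 2.46e-08), Tubb4b (-2.76 ± 0.11), the mitochondrial Chchd10 (-2.64 ± 0.15) and Asns (-2.35 ± 0.23) fell. The rises were led by Mpp7 (2.45 ± 0.46), the BMP target Id1 (2.39 ± 0.30), the histone Hist1h1c (2.06 ± 0.24), the WNT-pathway membrane protein Tmem108 (2.04 ± 0.12) and the zinc-finger gene Zfp516 (1.80 ± 0.25). Mpp7 was no longer called without chimera 1 (2.35, edgeR Benjamini-Hochberg adjusted p = 0.0528). Of 22 synapse genes 10 were lower and 2 higher (camera adjusted p = 0.0472, and adjusted p = 0.924 with an estimated correlation). Nrgn (-3.98 ± 0.27) and Nefl (-2.84 ± 0.37) were among the falls. Heat-shock genes were lower in 5 of 8 (camera adjusted p = 4.08e-05, and adjusted p = 0.863 with an estimated correlation). Hsp90aa1 (-1.81 ± 0.10) and Hspa8 (-1.14 ± 0.11) were among them. Oxidative phosphorylation genes were lower in 16 of 20 (17 adjusted over the list alone; camera adjusted p = 4.08e-05, and adjusted p = 0.924 with an estimated correlation), Cox5a (-1.14 ± 0.10) and Ndufb4 (-1.02 ± 0.10) among them. Astrocyte genes were lower in 5 of 9 (camera adjusted p = 0.0472, and adjusted p = 0.924 with an estimated correlation). Tubb3 (-1.29 ± 0.10), Fdps (-1.72 ± 0.10) and Ndn (-2.08 ± 0.12) fell, and Sox11 (1.21 ± 0.11), Jund (1.13 ± 0.13), Insig1 (1.24 ± 0.15) and Usp29 (0.80 ± 0.11) rose.

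Cycling mouse cells, held by cluster M23 in each library, had 9 of 20 cell-cycle, 5 of 13 astrocyte, 4 of 8 heat-shock and 8 of 20 oxidative phosphorylation genes lower in chimeras, with none of these lists called with an estimated correlation. Of 11286 genes, 1470 changed (463 higher, 1007 lower; edgeR, as above), and 908 without chimera 2. The homeobox gene Zfhx4 (2.48 ± 0.28), Vegfa (2.31 ± 0.39), Zfp236 (2.20 ± 0.31), Klf4 (2.18 ± 0.43) and the imprinted Plagl1 (1.86 ± 0.24) rose most. Apoe (-3.09 ± 0.11, edgeR Benjamini-Hochberg adjusted p = 8.16e-06) fell from 1599 CPM to 207, 209 and 201 CPM, and Tmem176b (-2.64 ± 0.27), the tetraspanin Cd9 (-2.54 ± 0.22), the creatine kinase Ckb (-2.45 ± 0.13) and Lxn (-2.45 ± 0.18) followed. Cell-cycle genes were lower in 9 of 20 and higher in 0 (11 lower adjusted over the list alone; camera adjusted p = 6.46e-05, and adjusted p = 0.395 with an estimated correlation). Mcm3 (-1.61 ± 0.15) and Pcna (-1.05 ± 0.17) were 2 of these. Astrocyte genes were lower in 5 of 13 (6 adjusted over the list alone; camera adjusted p = 1.01e-07, and adjusted p = 0.395 with an estimated correlation), including Sparcl1 (-2.35 ± 0.21). Heat-shock genes were lower in 4 of 8 (camera adjusted p = 0.00036, and adjusted p = 0.395 with an estimated correlation), including Hsp90aa1 (-1.38 ± 0.11). Oxidative phosphorylation genes were lower in 8 of 20 (13 adjusted over the list alone; camera adjusted p = 4.27e-05, and adjusted p = 0.583 with an estimated correlation), including Cox5a (-1.12 ± 0.13). Jund (1.23 ± 0.16) and Insig1 (1.28 ± 0.19) rose and Ndn (-1.56 ± 0.18) fell. In other mouse classes, 909 genes changed in radial glia or astrocytes (236 higher, 673 lower), held by M8 in the WT mouse and M26 in the chimeras, and 633 in oligodendrocyte-lineage cells (195 higher, 438 lower; edgeR, as above).

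**Figure D4:**
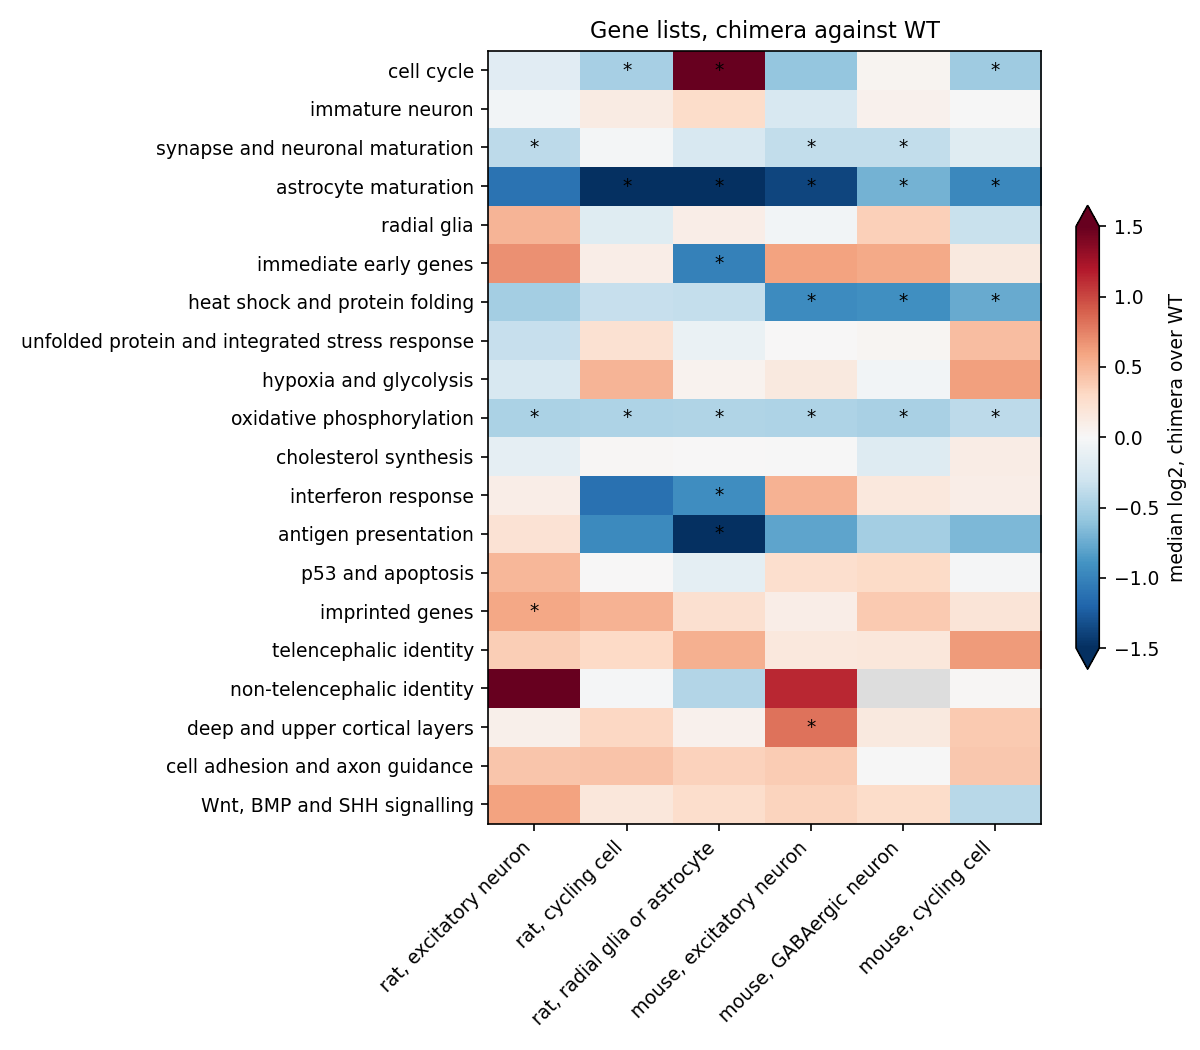
Median log2 difference between chimera and WT for 20 gene lists in the lead classes of rat and mouse cells, with a mark where camera with preset correlation called the list. Oxidative phosphorylation lies below 0 in all 6 fits. No list was called with an estimated correlation, a test that could hardly call one with 2 residual degrees of freedom.

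Whether rat and mouse cells changed alike was asked on genes present in both genomes. Most genes called in both species moved the same way in rat and mouse cells of chimeras. Nrgn, Tubb4b and Junb fell in excitatory neurons of both species, and Sox11, Map2 and Zdbf2 rose in both. In excitatory neurons 1875 genes were called in both comparisons, 97.8% of them in the same direction: 710 higher in both (217 from independent lists), 1123 lower in both (337 from independent lists) and 21 in each of the opposite combinations. The rat and mouse log2 differences had a Pearson r of 0.468 and a Spearman rho of 0.578 across 10628 genes, which are not independent replicates. Among genes called in both, 99.5% of 574 moved the same way in cycling cells, 98.998% of 499 in radial glia or astrocytes and 99.2% of 516 in GABAergic neurons. The rat and the mouse comparison have different WT libraries, but rat and mouse cells of a chimera share a library. Taking rat cells of one chimera and mouse cells of another, the mean r across well-expressed genes was 0.669 in excitatory neurons, 0.620 in cycling cells, 0.598 in radial glia or astrocytes and 0.561 in GABAergic neurons. Within the same chimera it was 0.709, 0.665, 0.643 and 0.597.

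A direct test of the difference between both comparisons found fewer genes. In excitatory neurons, several imprinted genes and Mrpl43 rose in rat cells relative to the change in mouse cells. Of 12486 shared genes, 336 differed (190 higher in the rat comparison, 146 lower; edgeR quasi-likelihood test on 8 summed profiles, Benjamini-Hochberg adjusted p under 0.05). The 8 profiles came from 5 animals, and the test had no animal block, so it ignored the pairing of rat and mouse cells of a chimera. With RLE size factors the split was 101 higher and 339 lower, because the median of all genes moved from 0.08 to -0.11, so single directions are relative to that shift. The calls depend on which chimeras are included: without chimera 2 there was 1 gene, Mrpl43, without chimera 1 there were 30 and without chimera 3 there were 399. Among the genes open to the naming rule, with a mean of at least 20 CPM, Mrpl43 (4.11 ± 0.15, edgeR Benjamini-Hochberg adjusted p = 4.19e-05) led. Pcbd2 (2.33 ± 0.30), Jund (2.24 ± 0.28), the cold-inducible Cirbp (2.20 ± 0.16) and Cbr1 (2.07 ± 0.27) followed. Under the same rule the lower side was led by Tmem44 (-2.61 ± 0.19), the endocytic Amph (-2.38 ± 0.43), the kinase subunit Prkar1b (-2.27 ± 0.29), Mical2 (-2.25 ± 0.24) and Hacd1 (-2.12 ± 0.35). Imprinted genes were higher in 7 of 19 and lower in 0 (10 higher adjusted over the list alone; median 0.99, camera adjusted p = 1.5e-08, and adjusted p = 0.235 with an estimated correlation), among them Commd1 (1.34 ± 0.14), Peg3 (1.29 ± 0.17), Usp29 (0.99 ± 0.15) and Sgce (1.14 ± 0.19). Junb differed by -1.39 ± 0.25, the endoplasmic-reticulum chaperone Hspa5 by 1.05 ± 0.14 and Asns by 1.54 ± 0.28. Without chimera 2 these genes kept their direction, with log2 values of 2.26 (Pcbd2), 2.24 (Jund), 2.21 (Cirbp), 2.19 (Cbr1), -2.62 (Tmem44), -2.36 (Amph), -2.25 (Prkar1b), -2.105 (Mical2), -2.33 (Hacd1), -1.29 (Junb), 1.09 (Hspa5), 1.39 (Asns), 1.33 (Commd1), 1.32 (Peg3), 1.065 (Usp29) and 1.11 (Sgce), but had edgeR Benjamini-Hochberg adjusted p from 0.134 to 0.207. Without chimera 1, Pcbd2, Jund, Cbr1, Amph, Hacd1, Junb, Hspa5, Asns, Peg3, Usp29 and Sgce had edgeR Benjamini-Hochberg adjusted p from 0.0575 to 0.107, and without chimera 3 Amph (-2.66) had 0.0534.

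In cycling cells 5 of 10561 genes differed (edgeR; 956 had an unadjusted p under 0.05, and DESeq2 called 20). These were Mrpl43 (4.83 ± 0.32, edgeR Benjamini-Hochberg adjusted p = 2e-05), the potassium-channel subunit Kcnmb4 (3.52 ± 0.35), Fam111a (2.71 ± 0.27) and Dhrs4 (2.39 ± 0.35) on the higher side and the actin nucleator Actr2 (-1.74 ± 0.26) on the lower. Without chimera 1 or chimera 2, Dhrs4 (2.44 and 2.55) and Actr2 (-1.75 and -1.64) were no longer called, and the counts were 5 and 4, against 12 without chimera 3. The astrocyte list was lower (median -0.87, 0 of 13 called; camera adjusted p = 0.00538, and adjusted p = 0.728 with an estimated correlation), but not at clustering resolution 2 (camera adjusted p = 0.475). In radial glia or astrocytes 96 of 11102 differed (65 higher, 31 lower), with 53 higher and 40 lower under RLE size factors, and 65, 14 and 242 without chimera 1, 2 and 3. Fam111a (4.49 ± 0.43), Mrpl43 (4.23 ± 0.34), the mitotic regulators Cdc20 (4.08 ± 0.50) and Plk1 (3.83 ± 0.73), and Tcte1 (4.39 ± 0.89) were higher, and Prrx2 (-5.54 ± 0.69), Tmem100 (-4.34 ± 0.41), Fscn1 (-3.26 ± 0.62) and Mgst1 (-3.11 ± 0.63) lower. The imprinted adaptor gene Grb10 also differed, with 0 CPM in rat cells of the chimeras and 5.30 CPM in the WT rat, but not without chimera 1 or 2 (edgeR Benjamini-Hochberg adjusted p = 0.0605 and 0.133). Cell-cycle genes were higher in 7 of 19 (14 adjusted over the list alone; median 1.97, camera adjusted p = 3.26e-20, and adjusted p = 0.379 with an estimated correlation), with Mki67 (2.39 ± 0.34) and Nusap1 (2.39 ± 0.35). Astrocyte genes were lower in 2 of 13 (camera adjusted p = 0.000625, and adjusted p = 0.379 with an estimated correlation), with Clu (-1.90 ± 0.29), and immature-neuron genes higher as a list with 0 of 11 called (camera adjusted p = 0.0404, and adjusted p = 0.727 with an estimated correlation). At clustering resolution 2, 0 of 18 cell-cycle genes were called (camera adjusted p = 0.267), with Mki67 at 0.76, Nusap1 at 0.46 and Cdc20 at 0.95, and Tcte1 (2.46), Fscn1 (-2.5002), Mgst1 (-2.45), Clu (-1.49) and Grb10 lost their call too. The astrocyte and immature-neuron lists were not called there (camera adjusted p = 0.155 for both). Jund differed by 2.12 ± 0.32. Without chimera 2, Mki67 (2.33), Nusap1 (2.44), Clu (-1.96), Jund (2.17), Plk1 (3.66), Tcte1 (3.69), Fscn1 (-3.00) and Mgst1 (-3.17) lost their call, and the last 4 did so without chimera 1 as well (3.54, 4.17, -3.38 and -2.54). Without chimera 3, Tcte1 had 6.89. In GABAergic neurons 230 genes differed (43 higher, 187 lower), in part between the different rat subtypes of the WT rat and the chimeras. A variant at the 3' end was not checked for Mrpl43, Jund and Fam111a here either.

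Rat and mouse cells of the same chimera, which share an environment, were compared with each other. Many genes differed: in excitatory neurons 9585 of 11528 shared genes (4645 higher in rat cells, 4940 lower; edgeR quasi-likelihood test with the animal as block), in cycling cells 6704 (3044 and 3660), in radial glia or astrocytes 6816 (3117 and 3699) and in GABAergic neurons 5860 (2391 and 3469). Part of this can come from annotation and mapping, which were not tested. The same test could not be run between the WT animals, so these counts do not show whether a shared environment made the cells more alike. The ribosomal genes Rpl39 and Rpl38 had 0 CPM in rat excitatory neurons of each chimera. Eif4ebp3 had 0 CPM in mouse excitatory neurons of each chimera against 51.0, 42.1 and 47.1 CPM in rat ones. Among genes counted in both genomes, the cytoskeletal Tmsb10 was higher in rat excitatory neurons (1.75 ± 0.05), the p53 target Ccng1 likewise (2.38 ± 0.07), and Sox11 (-2.67 ± 0.06), Nrgn (-3.17 ± 0.07), the layer genes Cux1 (-3.92 ± 0.11) and Cux2 (-2.62 ± 0.09), the deep-layer factor Tbr1 (-4.69 ± 0.15), the guidance receptor Robo1 (-2.42 ± 0.07) and the ligand Efna5 (-6.06 ± 0.14) were higher in mouse cells. Commd1 (2.01 ± 0.05) was higher in rat cells and the imprinted Snrpn (-3.75 ± 0.07) in mouse cells, each with an edgeR Benjamini-Hochberg adjusted p between 3.59e-09 and 4.77e-07 for the genes named here that are measured in both genomes. As lists, cell-cycle genes were higher in rat radial glia or astrocytes (13 higher and 2 lower of 19; camera adjusted p = 1.19e-13, and adjusted p = 0.843 with an estimated correlation) and layer genes lower in rat cycling cells (1 higher and 10 lower of 16; camera adjusted p = 0.0488, and adjusted p = 0.888 with an estimated correlation). Neither was called at clustering resolution 2 (camera adjusted p = 0.386 and 0.0692).

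The WT rat and the WT mouse gave the species difference to set beside this, with 1 animal each and no test. In excitatory neurons 568 of 6130 shared genes were at least 2-fold higher in the rat and 1274 in the mouse (30.05% together; r = 0.572 across genes). Cycling cells (30.01%), radial glia or astrocytes (32.2%) and GABAergic neurons (31.8%) had similar shares. On those genes, chimera cells lay nearer their own species than the other: 90.9% ± 1.03 (SD, n = 3) of the genes in rat and 92.5% ± 0.84 in mouse excitatory neurons, 87.6% ± 1.45 and 90.5% ± 1.47 in cycling cells, 83.9% ± 1.22 and 90.2% ± 0.70 in radial glia or astrocytes, and 80.6% ± 2.35 and 94.6% ± 0.20 in GABAergic neurons. The genes were picked by the gap between the same WT libraries, and each species was counted on its own annotation. A gene counted in only 1 genome lies nearer its own species in any environment. The shares nearer the own species, and the correlations that follow, therefore do not test whether cells kept their identity. Rat excitatory neurons of chimeras 1, 2 and 3 had r = 0.941, 0.946 and 0.941 across genes with the WT rat and 0.533, 0.530 and 0.533 with the WT mouse. Mouse excitatory neurons had r = 0.914, 0.918 and 0.927 with the WT mouse and 0.492, 0.495 and 0.498 with the WT rat.

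The remaining lists were called by camera in 0 of their fits in the lead classes of the 4 comparisons: radial glia genes, the unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol synthesis, p53 and apoptosis, telencephalic identity, cell adhesion and axon guidance, and Wnt, BMP and SHH signalling in 12 fits each, and non-telencephalic identity in 11. Fry, which tests whether a list moves 1 way without comparing it with other genes, called 0, 1, 2, 0, 1, 2, 3, 1 and 1 of these in the same order. At clustering resolution 2, camera called 3 of them: hypoxia and glycolysis in rat cycling cells (adjusted p = 0.0411), and radial glia genes and Wnt, BMP and SHH signalling in the cycling cells of the difference between comparisons (adjusted p = 0.0203 and 0.0107). The pluripotency and off-target lineage list had too few measured genes for a set test, so stray lineages were not tested as a list.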

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

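For the shared change and the few rat inhibitory neurons, the tests were chosen only after the result was seen, as was the test of the stem cell line for the imprinted genes. The tests of cross-mapping and of a single chimera library for the imprinted genes were written before.

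Genes whose change differed between the rat and the mouse comparison are listed here as a difference between groups: 336 in excitatory neurons, 5 in cycling cells, 96 in radial glia or astrocytes and 230 in GABAergic neurons (edgeR, Benjamini-Hochberg adjustment). The reporter tdTomato is listed as a signal outside the main comparisons, with 75.5%, 64.8% and 70.7% of rat cells marked in chimeras 1, 2 and 3, against 0 WT cells.

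The first pattern is the shared change: 1833 genes moved the same way in rat and mouse excitatory neurons of chimeras. For strain, cell line or sex as the whole cause, rat and mouse cells of different chimeras were paired, and their differences were related with a mean r of 0.669. Each pair used the same WT rat and WT mouse libraries, and genes that move the same way in both species already imply a positive r. The value therefore restates the pattern, and strain, cell line and sex stay open. Other neuron subtypes or maturity cannot be told apart from the chimera itself either. In cycling cells 93.1% of the genes kept the direction in both species, but counting this against maturity was wrong, because those cells come from the same libraries and an offset in maturity would move them too. In the deep-layer clusters alone, chosen after seeing the data, 98.3% of the genes (1707 of 1736) kept the direction in both species. This decides nothing, since these cells are part of those that gave the genes, and each of the clusters lay mostly in the WT animal or mostly in the chimeras (M1 and R7, M33 and R26), so subtype and maturity stay open. A library or handling batch that separates WT from chimera libraries cannot be told apart from the chimera itself, since 83.5% of the genes moved the same way in all 4 classes of both species and batch goes with group. An effect of growing in a chimera also stays open and was not tested.

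The second pattern is the rise of imprinted genes in rat excitatory neurons relative to mouse ones. The difference between comparisons called 7 members. In rat cells alone Commd1, Peg3, Sgce and Usp29 were called higher, Slc38a4 (0.62) and Snrpn (0.54) were higher without a call, and Ndn fell, less than in mouse cells. Mouse reads assigned to rat genes allow at most 3.80% of the rise of any of the first 6. A single chimera library is argued against by a median that stayed at 0.91 or more with each chimera left out. The lone WT rat and WT mouse libraries could not be left out, so an unusual WT library stays open. The number of called members did fall to 1 and 0 without chimeras 1 and 2. The stem cell line or strain cannot be told apart from the chimeric state, since by direction alone 5 of the 6 members measured were higher in the cycling cells of the difference too, with 0 called, and there is 1 line and 1 WT rat. In radial glia or astrocytes it was 6 of 6 and in GABAergic neurons 4 of 6. In mouse cells Slc38a4 (-3.43), Ndn, Commd1 and Snrpn fell, 4 of the 7, so part of the difference lies on the mouse side.

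The third pattern is the scarcity of rat striatal neurons in chimeras 2 and 3 and of rat GABAergic neurons in chimera 2. In chimera 1 the rat share of striatal neurons was 47.8% and moved to 72.2% and 56.4% at other resolutions, above that of its pooled neurons. For striatal cells alone in chimera 2, clustering fits as the cause, since the rat share rose to 27.1% at another resolution, and dissection cannot be told apart, with an upper limit of 39.1%. In chimera 3 neither can be told apart, because cells were few (up to 11.1% at another resolution, upper limit 48.3%). For GABAergic and striatal neurons pooled in chimera 2 (64 of 1316), clustering is argued against. The highest share at another resolution was 4.90%, against 31.8% for excitatory neurons. The highest upper limit was 6.22%, but this covers only the tissue that was sampled. It cannot show the rat share of tissue left out, so dissection cannot be told apart. A weaker entry of rat cells into ventral lineages stays open and was not tested.

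For rat against mouse cells within chimeras, without the block, 1 of 10 splits of the 6 libraries (the real one) called as many genes in each class: 8993 in excitatory neurons, 6188 in cycling cells and 6077 in radial glia or astrocytes, with 0 as the highest other count. The splits are too few for a share under 0.05.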

How the results depend on the processing

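A share counted as kept if it stayed within 1 SD between chimeras, and a count of called genes if it stayed within 1.5 times. The deep-layer clusters alone, the removal of cluster M33 and the lists at resolution 2 were chosen after seeing the data, and where values moved, the cause was not tested. Of 310 alternatives for shares and profiles 298 kept their value, of 2917 for single genes 2765 kept their call, 150 lost it and 2 reversed, and of 178 for counts of called genes 139 stayed. For single lists, 655 of 765 stayed, 75 lost and 35 gained a call. Depth and 1 WT animal per species limit all of these, and intermediate progenitors of the rat had no name at resolution 0.5. The rat share stayed between 39.1% and 43.5% under other filters and between 35.6% and 49.1% without a chimera.

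The mean rat share of striatal neurons, 17.6%, counted as kept only through its wide SD, with 36.8% at resolution 0.5 and 26.9% at resolution 2. Differences in class share moved at resolution 2 for rat GABAergic neurons (-20.4 to -27.9 points), cycling cells (1.42 to 3.18) and striatal neurons (-11.8 to -4.20), and for mouse cycling cells (2.12 to 1.76, and 1.74 at resolution 0.5), intermediate progenitors (-0.706 to 1.19) and radial glia or astrocytes (-4.86 to -3.56). With 1000 genes and 10% mitochondrial UMIs, cells of rat cluster R13 moved from -0.478 to -0.342, rat oligodendrocyte-lineage cells from -1.86 to -0.232 and mouse microglia from -0.825 to -0.641. At 5 CPM the share of genes nearer the own species was 88.4% in mouse radial glia or astrocytes and 94.0% in mouse GABAergic neurons. Unc5d (-0.0739, deep-layer clusters alone) and Tle4 (-0.23, without M33) reversed in mouse excitatory neurons.

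In rat cells against the WT rat, called genes were 703 (excitatory), 292 (cycling) and 1065 (radial glia or astrocytes) with glmTreat, 529 (cycling) and 946 (radial glia or astrocytes) with DESeq2, and, in radial glia or astrocytes, 1626 with thinned counts and 1633 at resolution 2. Leaving out a chimera gave 1850 to 4271, 645 to 1291 and 1644 to 2518. In mouse cells they were 717 (excitatory), 739 (GABAergic) and 252 (cycling) with glmTreat and 2133 (GABAergic) and 706 (cycling) with DESeq2, and 2056 to 4489 (excitatory) and 908 to 2144 (cycling) without a chimera. The difference between comparisons had 966 (DESeq2), 550 (20 CPM) and 15 (glmTreat) in excitatory neurons, with 1 to 399 without a chimera. In cycling cells it had 20 (DESeq2), 21 (no filter), 3 (glmTreat) and 8 each with RLE, doublets kept, 1000 genes and resolution 2, with 4 to 12 without a chimera. In radial glia or astrocytes it had 195 (no filter), 39 (thinned), 49 (glmTreat) and 27 (resolution 2), with 14 to 242 without a chimera. Within chimeras there were 5367 (excitatory) and 4406 (cycling) at 20 CPM and 4318 (cycling) with glmTreat, and without the animal as block 8993, 6188 and 6077. Camera called 38 lists, 0 with an estimated correlation, and 33 at resolution 2, and fry 41.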

Other observations

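The list of proteasome subunits was added after seeing that several fell, and its test was written before its result was seen. Of 34 subunit genes, 32, 31 and 32 were lower in rat excitatory neurons, cycling cells and radial glia or astrocytes of chimeras, and 34, 33 and 32 in mouse excitatory neurons, GABAergic neurons and cycling cells, with 0 higher in any. The median log2 differences were -1.14, -1.31, -1.002, -1.29, -1.18 and -1.18. With an estimated correlation and an adjustment over these 6 fits alone, it was lower in 6 of 6 (camera, Benjamini-Hochberg adjusted p from 0.0198 to 0.0224). Adjusted together with the other lists of each fit, an adjustment added after that result was seen, it was lower in 0 of 6 (camera, Benjamini-Hochberg adjusted p from 0.116 to 0.452). The list was chosen for members that had fallen in these same data, and the 6 fits share libraries, so the counts are not independent support. Over all genes, 1881 of 12333 were called lower in rat and 2369 of 13831 in mouse excitatory neurons. A decrease of the set relative to other genes cannot be told apart from correlated genes, since the call depends on the adjustment. Whether chimerism, batch or the WT animals underlie it was not tested.

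Genes of the Y chromosome differed between animals. Over all rat cells, Eif2s3y and Kdm5d had 0 UMIs in the chimeras and were at least 3582-fold and at least 469.9-fold lower than in the WT rat. Among mouse cells, chimera 2 had 77.5 CPM of Eif2s3y, 67.4 of Ddx3y, 28.4 of Kdm5d and 22.6 of Uty, while the WT mouse and chimeras 1 and 3 had 0 UMIs of the first 3 genes and 3, 1 and 4 UMIs of Uty. By these genes, sex differs between the WT rat and the rat cells of chimeras, and between the mouse cells of chimera 2 and those of the other libraries, so in rat cells it goes with the group. The rat locus AABR07039356.2 had 15369 UMIs in rat cells of chimeras and 3 in the WT rat (263, 209 and 237 against 0.0423 CPM). Whether it is a transgene, a locus of the line or a transcript of female cells was not checked.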
